A study of Homo sapiens with 12 samples.

How the data were processed

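RNA was measured in 12 samples of human peripheral blood B cells, 3 in each of the groups Naive, Memory, Sec and Orc, as the titles and cell type labels name them. Per the labels' protocols, mononuclear cells were isolated from normal leukopacks on a Ficoll gradient, B cells were enriched by magnetic selection for CD19, RNA was extracted with the Qiagen RNeasy Plus kit, and the labelled nucleotide was biotin UTP, read out with Cy3 streptavidin. The labels do not give the gates that separated the 4 groups.

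The values used are the authors' normalized intensity values for each probe and array, on a linear scale, as deposited. GenomeStudio 2010.3 is named in the submitters' processing notes. The normalization method is not given in the sources used here, and the values show its effect: all 12 arrays had the lowest intensity 64.8, the highest intensity 20372 and medians between 95.18 and 95.22, as after a quantile normalization. Whether background was subtracted is not given. Probes of genes not expected in blood had medians of 87.1 to 88.7, so that a floor remains and fold changes of dim genes are understated. A table of non-normalized signals with detection p-values was not used, because its 24 sample columns (12 signal and 12 detection columns) have names that match no sample label. The planned background correction and normalization from those signals with neqc, and the planned detection p, could therefore not be used. The test was run on log2 of the deposited intensities instead.

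Of 47226 probes, 30111 had 1 gene symbol in the platform annotation, 8 had several and 17107 had none. Gene identifiers of 30072 probes matched the RefSeq gene table, and no symbol needed updating. No coordinates are given, since the sources used here name no genome build. A probe was taken as above background on an array where less than 0.01 of the 455 probes of olfactory receptor genes, which are not expected in blood cells, were at or above its intensity; their 99th percentile was 110.6 to 142.5. Probes above background on at least 3 of 12 arrays were kept (9925 probes with a single symbol), and each gene was represented by its kept probe with the highest mean log2 intensity, which left 7889 genes, 1712 of them with over 1 kept probe. Since each group has 3 arrays, a gene could pass the filter through 1 group alone. For no named gene did another kept probe pass in the opposite direction. Genes linked to the Y chromosome, XIST, TSIX and JPX were left out. CD19 and the immunoglobulin constant region genes had no probe that could be used by name and were not analysed here.

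Log2 intensities were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per group, all 12 arrays sharing the estimate of spread (8 residual and 4.33 prior degrees of freedom). The comparisons were the 6 pairs of groups, the mean of Sec and Orc against the mean of Naive and Memory, and an F test over the 4 groups, each with Benjamini-Hochberg adjustment over the 7889 genes and a threshold of 0.05. Comparisons with a group in common share that group's chance values, so no overlap of calls between comparisons was counted. Where no array of a group was above background for the probe that represents a gene, and at least 1 array of the other group was, the change is given as at least N-fold. Other probes of the gene were not checked for this. This is the brighter group's mean against the mean of the higher of the dim probe's own intensity and the lowest intensity above background on each array. Where neither group was above background on any array, no change is given. Each of 22 fixed gene lists was described by its members past the threshold over all genes and adjusted over the list alone. The 18 lists with at least 5 measured genes were tested with camera (correlation preset at 0.01, and again with the correlation estimated), with Benjamini-Hochberg adjustment over the 18 lists. A list score is the mean log2 intensity of its measured genes. The tested lists hold pan B cell, naive B cell, memory B cell, plasmablast, unfolded protein response, B1-associated, CD11c and T-bet B cell, antigen presentation and costimulation, cytokine and chemokine, B cell receptor signalling, T cell, monocyte, NK cell, platelet, erythroid, type I interferon, immediate early and ribosomal protein genes. The lists of immunoglobulin constant region, cell cycle, plasmacytoid dendritic cell and neutrophil genes had 0, 2, 2 and 3 measured genes and were not tested as lists.

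The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. Genes were named as follows: the 6 largest rises and the 6 largest falls among genes past the threshold whose groups did not overlap, up to 3 members of each list whose test passed, in its direction and by smallest p, and 1 of any other list, and a fixed set of gate and marker genes (CD19, MS4A1, CD27, SPN, CD70, ITGAM, CD5, CD3E, CD14, PRDM1, JCHAIN and TCL1A). Genes that vary by inherited presence or absence, highly polymorphic HLA genes and unnamed loci were not named. The fit was tested on simulated data for Orc against Memory with 7889 genes and 200 changed genes, and recovered 76%, 94%, 94% and 98% of the 50 genes changed by 1, 1.5, 2 and 3 on the log2 scale, each with the right sign, with 4 false calls. In the same simulation the list test called the 1 raised list and none of 20 random lists. The simulated genes varied independently of each other, so this does not show how the list test behaves on lists of correlated genes. Alternatives covered the filter, the probe rule, array weights, the arrays in the fit, each array left out in turn, a fold threshold, the replicate number as a block, normexp background correction (offset 16), median centring and the removal of marker genes of other cell types. Permutation tests of list scores and the figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No slide or scan date was given in the sources used here.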

Results

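Messenger RNA was measured on 12 Illumina bead arrays of human B cell subsets from peripheral blood. The labels name 4 groups of 3 arrays each: naive B cells, memory B cells, and groups named Sec and Orc. The title of the series concerns the identification of human B1 cells, an innate-like B cell population best known from mice. Naive and memory cells are conventional subsets, so Sec and Orc are taken here as the candidate B1 groups. The labels neither spell out these names nor give the sorting gates. As background not given in the labels, published work on circulating human B1 cells defined them by surface CD20, CD27 and CD43, the last encoded by SPN, and divided them by CD11b, encoded by ITGAM. The authors' normalized intensities ran from 64.8 to 20372 on each array, and between 16.6% and 24.6% of the probes lay above background. After the filter, 7889 genes were compared. Whether the 3 arrays of a group came from separate donors is not given in the sources used here, so the p-values measure only the spread between these samples, which may be technical. Changes are differences of mean log2 intensity ± the standard error (SE) of the limma fit, with n = 3 arrays per group. Levels are means of log2 intensity ± SD of 3 arrays. The number of arrays limits the precision.

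The Orc arrays stood apart from the other 9. Across the 7889 genes the mean correlation was 0.98 between Orc arrays, and 0.81, 0.80 and 0.84 between Orc arrays and those of Naive, Memory and Sec. It was 0.97 between Naive arrays, 0.95 between Memory arrays and 0.94 between Sec arrays, 0.95 between Naive and Memory arrays, and 0.92 between Sec arrays and those of either group. Of the Sec arrays, 1 correlated more with each Memory array (0.94 to 0.95) than with the other Sec arrays (0.92 and 0.93). These correlations are across genes, which are not independent replicates. The first principal component held 60.8% of the variance and placed the 3 Orc arrays farthest to one side. The second held 12.1% and placed the 3 Sec arrays farthest to one side. Of 7889 genes, 3603 differed among the 4 groups by the F test of limma.

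**Figure D1:**
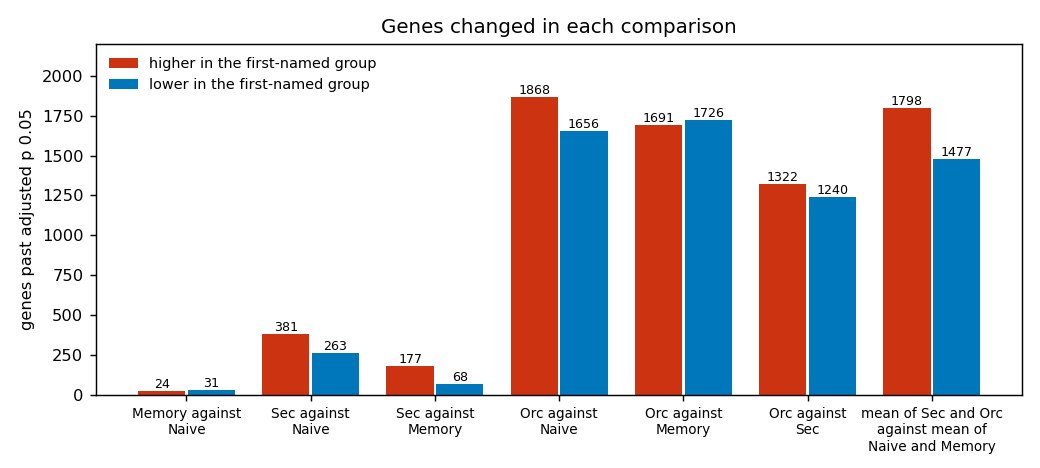
The vertical axis is the number of genes past an adjusted p of 0.05 of the 7889 tested, and each pair of bars is a comparison, red for genes higher and blue for genes lower in the group named first. The 4 comparisons that hold Orc changed between 2562 and 3524 genes, against 55 for Memory against Naive, 644 for Sec against Naive and 245 for Sec against Memory.

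Memory against Naive shows how the conventional subsets differ. Of 55 genes past the threshold, 24 were higher and 31 lower in Memory. AIM2, a sensor of cytosolic DNA, rose by 1.93 ± 0.19 (adjusted p = 0.00064) and CD70, the ligand of CD27, by 1.57 ± 0.17 (adjusted p = 0.00074). CD27, a TNF receptor family member that marks human memory B cells, rose by 2.04 ± 0.37 (adjusted p = 0.027), and TNFRSF13B, a receptor for BAFF and APRIL, by 1.98 ± 0.35 (adjusted p = 0.027). TCL1A, a co-activator of AKT kinase found in naive B cells, changed by -2.65 ± 0.22 (adjusted p = 0.00026) and the interleukin 4 receptor chain IL4R by -2.47 ± 0.27 (adjusted p = 0.00091). Other large falls were those of YBX3, at -2.35 ± 0.31, of SPRY1, an inhibitor of receptor tyrosine kinase signalling, at -2.32 ± 0.25, and of the zinc finger transcription factor gene ZBTB16, at -1.68 ± 0.26, with adjusted p up to 0.0093.

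Of the naive B cell list, 8 of 13 measured genes fell, and 11 fell when adjusted over the list alone, with a list median of -1.42 (list test adjusted p = 5.1e-23, 0.0029 with an estimated correlation). TCL1A, IL4R and BCL7A, at -1.59 ± 0.15, were among them. Of the memory B cell list, 6 of 19 genes rose, and 12 rose when adjusted over the list alone, with a median of 0.85 (list test adjusted p = 6.9e-16, 0.0029 with an estimated correlation). No gene of the pan B cell list (16 measured, median -0.05) or of the T cell list (16 measured, near background in both groups, median -0.06) passed. The monocyte list lay lower in Memory with no member past the threshold (list test adjusted p = 0.0015, 0.87 with an estimated correlation), and so did the platelet list (list test adjusted p = 0.0008, 0.59 with an estimated correlation). The B1-associated list, with 1 of 12 genes higher and 1 lower in Memory against Naive, did not pass (list test adjusted p = 0.68). Of these genes 2 rose and 1 fell when adjusted over the list alone. Among genes of the published gates, SPN changed by -0.20 ± 0.26 (adjusted p = 0.82) and ITGAM by 0.32 ± 0.26 (adjusted p = 0.71), neither past the threshold.

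The count for Memory against Naive was 30, 20 and 31 without Naive replicate 1, 2 and 3, and 32, 25 and 169 without Memory replicate 1, 2 and 3. It was 100 without Sec replicate 2 and 36 without Orc replicate 2 or Orc replicate 3. CD27 lost its call without Naive replicate 1, Naive replicate 2, Naive replicate 3, Memory replicate 2 and Orc replicate 3, and with no filter and with only the 6 arrays compared (adjusted p up to 0.14 over its alternatives). TNFRSF13B lost it without Naive replicate 1, Naive replicate 2, Naive replicate 3, Memory replicate 1 and Memory replicate 2, and with no filter (adjusted p up to 0.14 over its alternatives), and ZBTB16 without Naive replicate 2 and Memory replicate 2 (adjusted p up to 0.073 over its alternatives). AIM2, CD70, TCL1A, IL4R, YBX3, SPRY1 and BCL7A kept theirs under every alternative in which they were tested. A gene that a setting dropped had no result there and could not lose its call. Of 7889 genes, 15.4% had groups that did not overlap, where chance gives 10%.

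**Figure D2:**
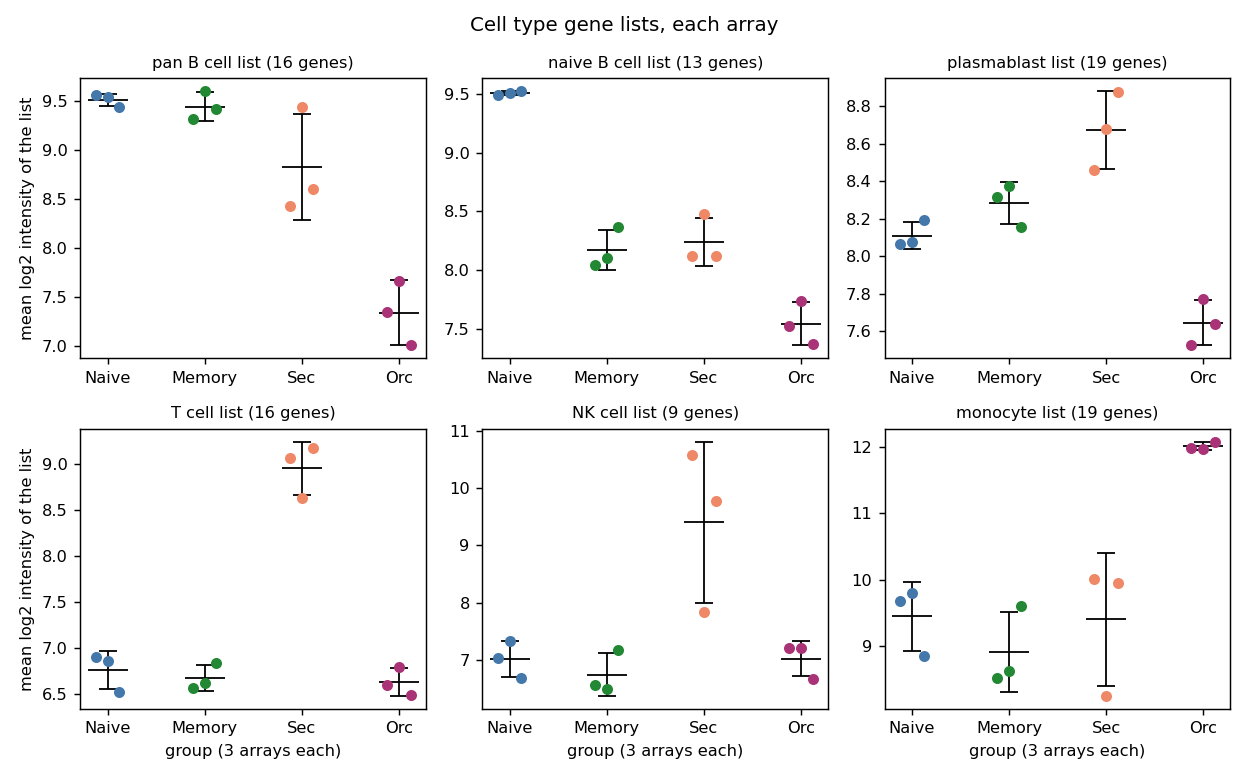
Each point is an array, placed by group on the horizontal axis and by the mean log2 intensity of a gene list on the vertical axis, which does not start at 0, with horizontal bars for the mean and error bars for the SD of 3 arrays. The T cell and NK cell lists were highest on the Sec arrays and the monocyte list on the Orc arrays, where the pan B cell list was lowest.

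Sec against Naive asks how the first candidate B1 group differs from naive B cells. Of 644 genes, 381 were higher and 263 lower in Sec. The largest rises included many genes of T cells. CD247, the zeta chain of the T cell receptor complex, rose by 3.83 ± 0.38 (adjusted p = 9.8e-05), and the interleukin 7 receptor chain IL7R by 3.33 ± 0.24 (adjusted p = 1.6e-05). IL32, MAL and PRKCH rose by 3.38 ± 0.31, 3.30 ± 0.27 and 3.11 ± 0.30, with adjusted p up to 8.9e-05. CD3D, not above background on any Naive array, was at least 9.7-fold higher (adjusted p = 1.7e-06). CD27 rose by 2.43 ± 0.37 (adjusted p = 0.0024). Large falls were those of TCL1A, at -2.04 ± 0.22, SPRY1, at -1.98 ± 0.25, the activation marker CD83, at -1.79 ± 0.16, and IL4R, at -1.78 ± 0.27, with adjusted p up to 0.0027.

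All 16 measured T cell genes rose, and all 16 when adjusted over the list alone, with a median of 2.42 (list test adjusted p = 9.2e-26, 0.0087 with an estimated correlation). BCL11B, a transcription factor of the T lineage, rose by 2.98 ± 0.21 (adjusted p = 1.6e-05), and CD3E was at least 5.4-fold higher (adjusted p = 2.9e-05). Of the NK cell list, 7 of 9 rose, and 8 when adjusted over the list alone (list test adjusted p = 1.2e-07, 0.19 with an estimated correlation). The granzyme gene GZMA, at least 5.65-fold higher, and KLRB1, at 3.04 ± 0.44 (adjusted p = 0.0017), were among them. The filter keeps a gene above background on 3 arrays, and CD3E was above background only on the 3 Sec arrays. Members of the T cell and NK cell lists that were dim elsewhere could thus enter through Sec alone. Their counts and list tests are therefore partly set by the filter, here and in each comparison with Sec. No list was tested without the filter. None of 19 monocyte genes passed (median -0.08, list test adjusted p = 0.51), and CD14, a surface receptor of monocytes, changed by -0.58 ± 0.51 (adjusted p = 0.53).

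Of the naive B cell list, 11 of 13 genes fell, and 13 when adjusted over the list alone (list test adjusted p = 8.4e-15, 0.0087 with an estimated correlation). Of the memory B cell list, 13 of 19 rose, and 15 when adjusted over the list alone (list test adjusted p = 2.5e-10, 0.0087 with an estimated correlation), with the integrin chain gene ITGB1 at 1.79 ± 0.25. The T cell list rose on the same arrays, and T cells also express CD27 of the memory B cell list. The rise of the memory B cell list therefore cannot be assigned to B cells alone. The plasmablast list rose in 8 of 19 genes. Adjusted over the list alone, 10 rose and 1 fell (list test adjusted p = 0.00023, 0.12 with an estimated correlation). Its members SEC11C, a signal peptidase subunit, FKBP11, a prolyl isomerase of the secretory pathway, and JCHAIN, which joins IgM and IgA into polymers, rose by 1.28 ± 0.16, 1.43 ± 0.18 and 1.97 ± 0.37. In the pan B cell list, 5 of 16 genes fell, and 7 when adjusted over the list alone (list test adjusted p = 2.9e-06, 0.2 with an estimated correlation). The BAFF receptor gene TNFRSF13C changed by -1.60 ± 0.27 (adjusted p = 0.0046) and the inhibitory receptor gene CD22 by -1.09 ± 0.20 (adjusted p = 0.0076).

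Of 12 B1-associated genes, 3 rose and 1 fell in Sec against Naive, and 6 rose and 3 fell when adjusted over the list alone (list test adjusted p = 0.026, 0.12 with an estimated correlation). CD5, a surface protein of T cells and of a subset of mouse B1 cells, was at least 3.19-fold higher (adjusted p = 0.0029). The T cell list rose too, so the rise of CD5 cannot be assigned to B1 cells here. LGALS1, which encodes galectin-1 and is on the memory B cell list too, rose by 1.45 ± 0.18, and the inhibitory receptor gene CTLA4 was at least 1.22-fold higher. SPN changed by 0.82 ± 0.26 (adjusted p = 0.071) and ITGAM by 0.50 ± 0.26 (adjusted p = 0.27), neither past the threshold. SPN gained a call under 2 of 21 alternatives: with array weights, and without Sec replicate 2. The B cell receptor signalling list fell in 3 of 18 genes, and in 4 when adjusted over the list alone (list test adjusted p = 0.0016, 0.26 with an estimated correlation). The antigen presentation list fell in 3 of 17 genes and rose in 1. Adjusted over the list alone, 5 fell and 1 rose (list test adjusted p = 0.0027, 0.14 with an estimated correlation), with CD40 at -0.90 ± 0.17. The immediate early list fell in 1 of 19 genes, NFKBIA, by either adjustment (list test adjusted p = 0.0068, 0.48 with an estimated correlation). Its scores were 10.53, 9.52 and 10.45 on Sec replicate 1, 2 and 3, against 10.25 to 10.72 in Naive. Only Sec replicate 2 lay below the Naive arrays.

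The count for Sec against Naive was 316 and 262 without Naive replicate 1 and 3, and 340 and 243 without Sec replicate 1 and 3. NFKBIA lost its call without Naive replicate 1, Naive replicate 3, Sec replicate 1, Sec replicate 2, Sec replicate 3 and Orc replicate 2, and with no filter and with only the 6 arrays compared (adjusted p up to 0.14 over its alternatives). CD247, IL7R, IL32, MAL, PRKCH, CD3D, CD3E, CD5, CD27, TCL1A, CD83, IL4R, JCHAIN, SEC11C, FKBP11, TNFRSF13C and CD22 kept theirs under every alternative tried. Groups did not overlap in 28.1% of genes, where chance gives 10%.

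Sec against Memory sets Sec beside the other group with high CD27. CD27 stood at 9.01 ± 0.71 in Memory and 9.40 ± 0.70 in Sec, a difference of 0.39 ± 0.37 (adjusted p = 0.63) that did not pass. Of 245 genes, 177 were higher and 68 lower in Sec. IL7R rose by 3.83 ± 0.24 (adjusted p = 4.6e-06), CD3D by 3.70 ± 0.19 (adjusted p = 1.3e-06), IL32 by 3.65 ± 0.31 (adjusted p = 3.2e-05) and PRKCH by 3.51 ± 0.30 (adjusted p = 3.6e-05). NKG7, of cytolytic granules, rose by 3.56 ± 0.64 (adjusted p = 0.01). The falls included those of CD70, at -1.30 ± 0.17 (adjusted p = 0.0011), AIM2, at -1.12 ± 0.19 (adjusted p = 0.009), and the immediate early transcription factor gene EGR1, at -1.62 ± 0.36 (adjusted p = 0.033).

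All 16 T cell genes rose, by either adjustment over all genes or adjusted over the list alone, with a median of 2.70 (list test adjusted p = 1.3e-35, 0.0067 with an estimated correlation). BCL11B was at least 6.99-fold and CD3E at least 5.95-fold higher. Of the NK cell list, 7 of 9 rose, and 9 when adjusted over the list alone (list test adjusted p = 1.6e-11, 0.12 with an estimated correlation). Of 12 B1-associated genes 2 rose, CD5 by at least 3.52-fold and CTLA4 by at least 1.34-fold, and 4 rose when adjusted over the list alone (list test adjusted p = 0.018, 0.12 with an estimated correlation). As the T cell list rose on the same arrays, this rise cannot be told apart from that of T cell genes. SPN changed by 1.02 ± 0.26 (adjusted p = 0.053) and ITGAM by 0.19 ± 0.26 (adjusted p = 0.76), neither past the threshold. SPN gained a call under 4 of 21 alternatives: with array weights and normexp, and without Naive replicate 3 and Sec replicate 2. The plasmablast list rose in 3 of 19 genes. Adjusted over the list alone, 10 rose and 1 fell (list test adjusted p = 0.0006, 0.12 with an estimated correlation), with SEC11C at 0.73 ± 0.16 (adjusted p = 0.029) and JCHAIN, not past the threshold, at 0.82 ± 0.37 (adjusted p = 0.29). MANF, at 0.69 ± 0.11 (adjusted p = 0.0062), was the 1 gene of 16 that rose on the unfolded protein response list, where 3 rose and 1 fell when adjusted over the list alone (list test adjusted p = 0.018, 0.12 with an estimated correlation).

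In Sec against Memory the pan B cell list fell in 1 of 16 genes, TNFRSF13C at -1.28 ± 0.27 (adjusted p = 0.025), and in 6 when adjusted over the list alone (list test adjusted p = 6e-06, 0.26 with an estimated correlation). The B cell receptor signalling list fell in 2 of 18, and in 3 when adjusted over the list alone (list test adjusted p = 0.0011, 0.26 with an estimated correlation). Of 17 antigen presentation genes 2 fell, TNFSF9 at -0.91 ± 0.16 and CD40 at -0.78 ± 0.17, and 6 when adjusted over the list alone (list test adjusted p = 0.0025, 0.13 with an estimated correlation). EGR1 was the 1 of 19 immediate early genes that fell, and adjusted over the list alone 6 fell and 1 rose (list test adjusted p = 0.0006, 0.37 with an estimated correlation). The score of this list was 10.53, 9.52 and 10.45 on Sec replicate 1, 2 and 3, against 10.41 to 10.86 in Memory. Only Sec replicate 2 lay below the Memory arrays. The monocyte list lay higher in Sec with no member past the threshold (median 0.37, list test adjusted p = 0.039, 0.69 with an estimated correlation), as did the platelet list (median 0.50, list test adjusted p = 0.024, 0.43 with an estimated correlation). TNFRSF13C lost its call without Memory replicate 2, Sec replicate 1 and Sec replicate 3, and with no filter and with only the 6 arrays compared (adjusted p up to 0.14 over its alternatives), and CD40 without Memory replicate 1, Memory replicate 2, Sec replicate 1 and Sec replicate 3, and with only the 6 arrays compared (adjusted p up to 0.14 over its alternatives). EGR1 lost its call without Memory replicate 1, Memory replicate 2 and Orc replicate 2, and with no filter, with genes above background on all 12 arrays, with the replicate block and with only the 6 arrays compared (adjusted p up to 0.17 over its alternatives).

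The count for Sec against Memory was 105 and 130 without Memory replicate 1 and 2. It was 121, 772 and 89 without Sec replicate 1, 2 and 3, and 163 without Orc replicate 2. Sec replicate 2 had the lowest NK cell score of the 3 Sec arrays, 7.84 against 10.57 and 9.78, and the highest pan B cell score, 9.44 against 8.43 and 8.60. NKG7 lost its call without Memory replicate 1 and Sec replicate 3, and with only the 6 arrays compared (adjusted p up to 0.1 over its alternatives), and SEC11C without Memory replicate 1, Memory replicate 2 and Sec replicate 3, and with genes above background on all 12 arrays, with only the 6 arrays compared, with array weights and with normexp (adjusted p up to 0.17 over its alternatives). AIM2, MANF, CD5 and TNFSF9 lost theirs only with the 6 arrays compared alone. IL7R, CD3D, IL32, PRKCH, BCL11B, CD3E, CTLA4 and CD70 kept theirs under every alternative in which they were tested. None of these genes was tested with genes above background on all 12 arrays. Groups did not overlap in 17.3% of genes, where chance gives 10%.

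Orc against Naive asks the same of the second candidate group. Of 3524 genes, 1868 were higher and 1656 lower in Orc. The largest rises included genes that monocytes express. PLAUR, the urokinase receptor, rose by 3.33 ± 0.58 (adjusted p = 0.00055), VCAN, a proteoglycan made by monocytes, by 3.25 ± 0.58 (adjusted p = 0.00067), and IL1B by 3.16 ± 0.68 (adjusted p = 0.0024). PTGS2, the inducible cyclooxygenase, and FCER1G, a signalling chain of Fc receptors, rose by 3.17 ± 0.49 and 3.15 ± 0.75. The largest falls included B cell genes. CD79A, a signalling chain of the B cell receptor, changed by -4.34 ± 0.50 (adjusted p = 3.9e-05), FCMR, an Fc receptor for IgM, by -4.17 ± 0.45 (adjusted p = 2.7e-05), and the chemokine receptor gene CXCR5 by -3.89 ± 0.35 (adjusted p = 1.3e-05). VPREB3 and FCRLA changed by -3.78 ± 0.30 and -3.74 ± 0.39.

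All 19 measured monocyte genes rose, with a median of 2.74 (list test adjusted p = 1.3e-08, 0.54 with an estimated correlation). CD14 stood at 10.96 ± 0.73 in Naive and 13.70 ± 0.11 in Orc, and S100A8, a calcium-binding protein of myeloid cells, rose by 2.88 ± 0.30 (adjusted p = 2.4e-05). Of the pan B cell list, 15 of 16 fell, with a median of -2.11 (list test adjusted p = 1.1e-08, 0.4 with an estimated correlation). In the naive B cell list 12 of 13 genes fell (list test adjusted p = 1.1e-08, 0.086 with an estimated correlation), TCL1A at -3.30 ± 0.22. The B cell receptor signalling list fell in 9 of 18 genes and rose in 1 (list test adjusted p = 0.015, 0.55 with an estimated correlation). Of the memory B cell list, 11 of 19 rose and 2 fell (list test adjusted p = 0.014, 0.4 with an estimated correlation). LGALS1, at 2.61 ± 0.18, and the annexin gene ANXA2, at 2.26 ± 0.21, were among its rises, and both are also expressed by myeloid cells. Of 17 ribosomal protein genes 6 fell, RPL13A at -0.85 ± 0.13 among them (list test adjusted p = 0.024, 0.54 with an estimated correlation). The counts of these 6 lists were the same when adjusted over the list alone, as were those of the cytokine and chemokine list, where 6 of 14 rose and 6 fell (median -0.31, mean 0.18 of opposite sign, list test adjusted p = 0.93).

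ITGAM rose in Orc against Naive by 2.02 ± 0.26 (adjusted p = 8.4e-05). SPN, at 0.67 ± 0.26 (adjusted p = 0.051), and CD27, at -0.36 ± 0.37 (adjusted p = 0.46), did not pass. SPN gained a call under 9 of 21 alternatives: with the replicate block, only the 6 arrays compared, array weights, normexp and removal of marker genes of other cell types, and without Naive replicate 2, Sec replicate 1, Sec replicate 2 and Orc replicate 3. CD5 was above background on no Naive or Orc array, so no change is given. The B1-associated list, with 6 of 12 genes higher and 3 lower in Orc against Naive, did not pass (list test adjusted p = 0.3). Of these genes 7 rose and 3 fell when adjusted over the list alone. JCHAIN changed by -1.69 ± 0.37 (adjusted p = 0.0028), and the early activation gene CD69 by -2.74 ± 0.28. The T cell list, near background in both groups, had a median of -0.08 (list test adjusted p = 0.55). Its 1 gene of 16 past the threshold was CD6, at -0.91 ± 0.34 (adjusted p = 0.046), and none passed when adjusted over the list alone. CD6 lost its call without Naive replicate 1, Naive replicate 2, Memory replicate 2, Sec replicate 1, Orc replicate 1 and Orc replicate 3, and with no filter, with the weaker background limit and with the replicate block (adjusted p up to 0.17 over its alternatives). The count was between 2959 and 3673 when each array was left out in turn. Groups did not overlap in 57.7% of genes, where chance gives 10%.

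Orc against Memory compares Orc with a group of high CD27. Of 3417 genes, 1691 were higher and 1726 lower in Orc. VCAN rose by 4.08 ± 0.58 (adjusted p = 0.00015), the growth factor gene HBEGF by 3.93 ± 0.67 (adjusted p = 0.00054) and the myeloid transcription factor gene CEBPD by 3.90 ± 0.81 (adjusted p = 0.002). CXCR5 changed by -4.08 ± 0.35 (adjusted p = 1.2e-05), CD79A by -4.03 ± 0.50 (adjusted p = 6.2e-05) and the lymphotoxin gene LTB by -4.01 ± 0.39 (adjusted p = 1.8e-05). The Src family kinase gene BLK changed by -3.73 ± 0.40. CD27 stood at 6.61 ± 0.23 in Orc, above background on 1 of 3 arrays, a change of -2.40 ± 0.37 (adjusted p = 0.00026). CD70 was above background on no Orc array and at least 3.37-fold lower (adjusted p = 7.5e-06). JCHAIN stood at 6.82 ± 0.49 in Orc, a change of -2.84 ± 0.37 (adjusted p = 9.4e-05).

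All 19 monocyte genes rose, with a median of 3.25 (list test adjusted p = 1.4e-10, 0.46 with an estimated correlation), and all 16 pan B cell genes fell, with a median of -1.65 (list test adjusted p = 3e-08, 0.46 with an estimated correlation). CD14 rose by 3.28 ± 0.51 (adjusted p = 0.00028), S100A8 by 3.52 ± 0.30 (adjusted p = 1.1e-05) and ITGAM by 1.70 ± 0.26 (adjusted p = 0.00027). SPN rose by 0.87 ± 0.26 (adjusted p = 0.016), and lost its call without Memory replicate 1, Memory replicate 2 and Orc replicate 1 (adjusted p up to 0.074 over its alternatives). The monocyte list rose on the same arrays, so the rises of SPN and ITGAM cannot be assigned to B1 cells here. MS4A1, which encodes CD20, was measured by a dim probe and was at least 1.59-fold lower (adjusted p = 0.044). It lost its call without Naive replicate 1, Naive replicate 2, Naive replicate 3, Memory replicate 1, Memory replicate 2, Orc replicate 1, Orc replicate 2 and Orc replicate 3, and with no filter, with the weaker background limit and with the replicate block (adjusted p up to 0.18 over its alternatives). The naive B cell list fell in 8 of 13 genes and rose in 1 (list test adjusted p = 0.025, 0.46 with an estimated correlation). The B cell receptor signalling list fell in 9 of 18 (list test adjusted p = 0.02, 0.56 with an estimated correlation), and the ribosomal protein list in 6 of 17 (list test adjusted p = 0.012, 0.46 with an estimated correlation). Of the memory B cell list, 8 of 19 rose and 9 fell (list test adjusted p = 0.96), and of the plasmablast list 4 of 19 rose and 9 fell (list test adjusted p = 0.18), PIM2 at -2.24 ± 0.17 among the falls. The counts of these 7 lists were the same when adjusted over the list alone. The B1-associated list, with 6 of 12 genes higher and 1 lower in Orc against Memory, did not pass (list test adjusted p = 0.18). Of these genes 6 rose and 2 fell when adjusted over the list alone. By limma no T cell gene passed (median -0.03), nor did any NK cell gene (median 0.16). Of the 16 and 9 genes, 0 were above background on all Naive and Memory arrays, so small rises would not be detectable. The count was between 2804 and 3579 when each array was left out in turn, and groups did not overlap in 55.2% of genes, where chance gives 10%.

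**Figure D3:**
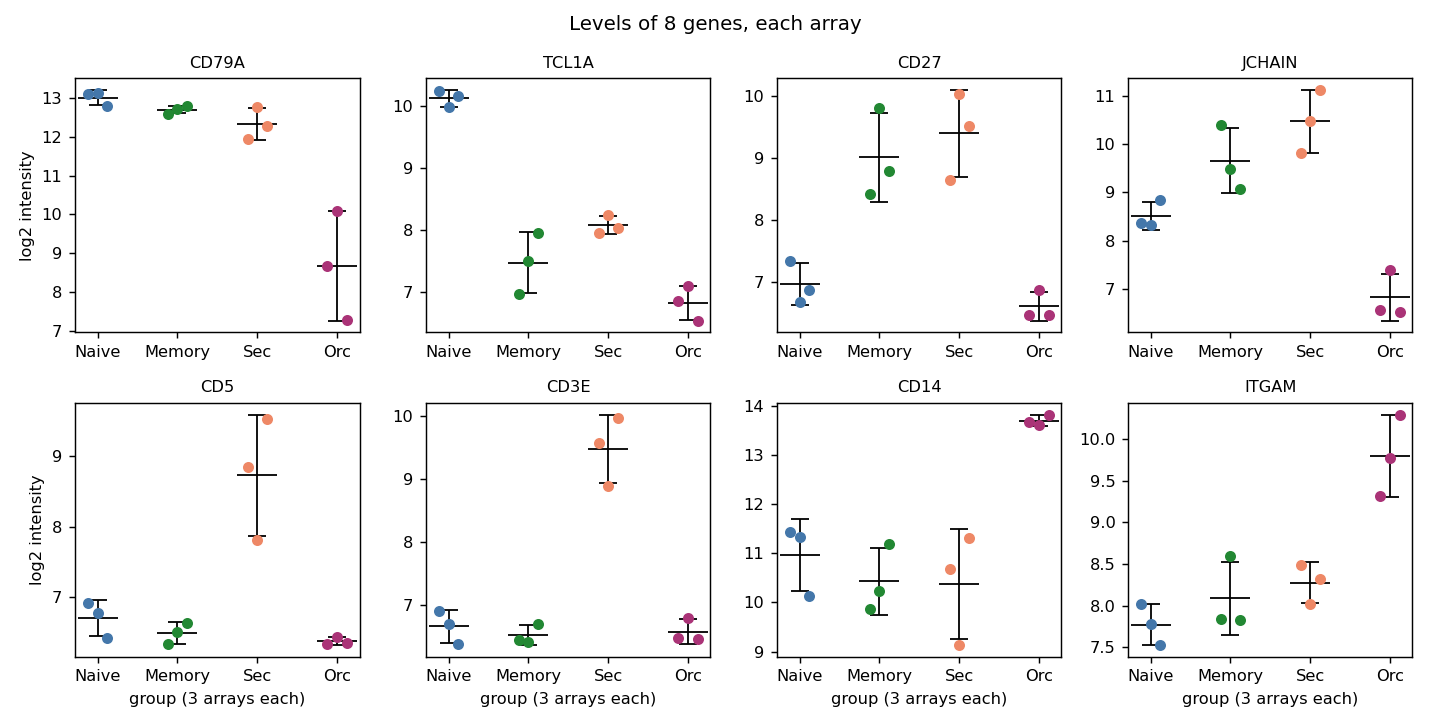
Each point is an array, placed by group on the horizontal axis and by the log2 intensity of the gene on the vertical axis, which does not start at 0, with horizontal bars for the mean and error bars for the SD of 3 arrays. CD27 was high in Memory and Sec, CD5 and CD3E in Sec, and CD14 and ITGAM in Orc, while CD79A and JCHAIN were lowest in Orc.

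Orc against Sec tests how the candidate B1 groups differ from each other. Of 2562 genes, 1322 were higher and 1240 lower in Orc. CXCL8, a chemokine that attracts neutrophils, rose by 3.84 ± 0.52 (adjusted p = 0.0002), IL1B by 3.83 ± 0.68 (adjusted p = 0.0011) and VCAN by 3.39 ± 0.58 (adjusted p = 0.00082). CD247 changed by -3.96 ± 0.38 (adjusted p = 2.8e-05), CD3D by -3.74 ± 0.19 (adjusted p = 1.1e-06) and FCMR by -3.92 ± 0.45 (adjusted p = 7e-05). IGLL1, a surrogate light chain gene, changed by -4.54 ± 0.41. Its probe stood at 12.45 ± 0.30 in Naive, 12.42 ± 0.38 in Memory, 13.38 ± 0.25 in Sec and 8.84 ± 1.09 in Orc. Whether the probe reads this gene alone was not tested. ITGAM was higher in Orc by 1.52 ± 0.26 (adjusted p = 0.00091), CD27 changed by -2.79 ± 0.37 (adjusted p = 0.00017), and CD5 was at least 3.61-fold lower (adjusted p = 0.00018). SPN, at -0.15 ± 0.26 (adjusted p = 0.69), and PRDM1, the transcription factor Blimp-1, at 0.05 ± 0.18 (adjusted p = 0.87), did not pass.

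Of the monocyte list, 18 of 19 genes rose, and 19 when adjusted over the list alone (median 2.76, list test adjusted p = 8.2e-12, 0.33 with an estimated correlation). All 16 T cell genes fell, by either adjustment (median -2.66, list test adjusted p = 1.5e-14, 0.11 with an estimated correlation). Of the NK cell list, 8 of 9 fell, and 9 when adjusted over the list alone (list test adjusted p = 0.00016, 0.39 with an estimated correlation). Of the pan B cell list, 11 of 16 fell, and 12 when adjusted over the list alone (list test adjusted p = 2.8e-06, 0.33 with an estimated correlation). The naive B cell list fell in 8 of 13 genes and rose in 1, with 11 lower when adjusted over the list alone (list test adjusted p = 0.0011, 0.33 with an estimated correlation). The plasmablast list fell in 10 of 19 and rose in 1 (list test adjusted p = 0.0011, 0.33 with an estimated correlation), and the ribosomal protein list fell in 5 of 17 (list test adjusted p = 0.0029, 0.33 with an estimated correlation), the same when adjusted over the list alone. JCHAIN changed by -3.66 ± 0.37 and ITM2C by -2.87 ± 0.29, and FKBP11 was above background on no Orc array and at least 3.66-fold lower. The immediate early list rose in 10 of 19 genes and fell in 3, with 11 and 4 when adjusted over the list alone (list test adjusted p = 0.009, 0.65 with an estimated correlation). ATF3 rose by 2.18 ± 0.25 and EGR1 by 2.42 ± 0.36. The B1-associated list, with 3 of 12 genes higher and 2 lower in Orc against Sec, did not pass (list test adjusted p = 0.78). Of these genes 4 rose and 2 fell when adjusted over the list alone. The count was between 1913 and 2653 when each array was left out in turn, and groups did not overlap in 51.6% of genes, where chance gives 10%.

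The mean of Sec and Orc against the mean of Naive and Memory asks how both candidate groups differ on average. Of 3275 genes, 1798 were higher and 1477 lower. A pooled rise can come from 1 group, as for CD3D, at 1.78 ± 0.14 (adjusted p = 1.6e-05), whose level in Orc was 6.59 ± 0.25, and for CD14, at 1.35 ± 0.36 (adjusted p = 0.0098), whose level in Sec was 10.38 ± 1.13. The genes that follow had 6 arrays on each side that did not overlap. The adaptor gene FYB1 rose by 2.31 ± 0.21 (adjusted p = 3.8e-05), the adaptor gene HCST by 2.23 ± 0.25 (adjusted p = 7.5e-05), and the GTPase gene GIMAP7 by 1.97 ± 0.19 (adjusted p = 3.8e-05). STING1, an adaptor of DNA sensing, rose by 1.82 ± 0.16 (adjusted p = 3.5e-05). As background, T cells and myeloid cells both express FYB1 and HCST. CXCR5 changed by -2.52 ± 0.25 (adjusted p = 4.6e-05), VPREB3 by -2.47 ± 0.21 (adjusted p = 3.5e-05), the surface receptor gene LY9 by -2.15 ± 0.15 (adjusted p = 1.6e-05) and GNG7 by -2.12 ± 0.20 (adjusted p = 3.8e-05). Sides did not overlap in 5.48% of genes, where chance gives 0.216%.

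On this average all 16 T cell genes rose (list test adjusted p = 1.1e-08, 0.21 with an estimated correlation), as did all 19 monocyte genes (list test adjusted p = 1.3e-07, 0.33 with an estimated correlation). Of the pan B cell list, 15 of 16 fell (list test adjusted p = 6.5e-09, 0.21 with an estimated correlation), and of the naive B cell list 11 of 13 (list test adjusted p = 7.9e-07, 0.2 with an estimated correlation). In the B cell receptor signalling list 9 of 18 fell (list test adjusted p = 0.0018, 0.33 with an estimated correlation). Of 12 B1-associated genes 8 rose and 2 fell (list test adjusted p = 0.041, 0.21 with an estimated correlation), with LGALS1 at 1.59 ± 0.12, ITGAM at 1.10 ± 0.19 and SPN at 0.84 ± 0.18 (adjusted p = 0.0029). The counts of these 6 lists were the same when adjusted over the list alone. As background, LGALS1 and ITGAM are also expressed by myeloid cells and SPN by T cells. The rise of the B1-associated list cannot be told apart from that of the T cell and monocyte lists. Of the NK cell list, 7 of 9 rose, and 8 when adjusted over the list alone (list test adjusted p = 0.0039, 0.5 with an estimated correlation). The memory B cell list rose in 10 of 19 genes and fell in 4, with 10 and 5 when adjusted over the list alone (list test adjusted p = 0.041, 0.33 with an estimated correlation). Of 17 ribosomal protein genes 3 fell, and 2 when adjusted over the list alone (list test adjusted p = 0.041, 0.47 with an estimated correlation). CD27, at 0.02 ± 0.26 (adjusted p = 0.97), did not pass, and CD70 changed by -0.92 ± 0.12 (adjusted p = 0.00015). The count was between 2804 and 3517 when each array was left out in turn.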

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

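The tests below, the splits of the arrays included, were all chosen after the result was seen. Probes with no gene symbol were outside the comparisons of genes: of 2155 such probes above background on at least 3 arrays, 815 changed across the 4 groups, 838 in Orc against Naive (294 higher and 544 lower) and 17 in Memory against Naive. Without a symbol they cannot be assigned to a gene here, and no explanation was tested.

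On the Orc arrays the monocyte list was higher and the pan B cell list lower than on any other array, at scores of 12.01 ± 0.06 and 7.34 ± 0.33 against 8.92 ± 0.60 and 9.44 ± 0.14 in Memory. A smaller share of B cell RNA that raised every other cell type alike is argued against, for platelets only, by the 5 platelet genes above background on all Naive arrays. Their median changed by -0.70 from Naive to Orc, with 0.86 as the highest, beside 2.74 for the monocyte list. Against Memory, 6 of 7 measured platelet genes were higher in Orc, 1 past the threshold. Their median was 0.07 and the highest 2.20, beside 3.25 for the monocyte list. The platelet score was 7.92 ± 0.43 in Naive and 7.20 ± 0.38 in Memory, so the sign depends on the reference group. The T cell list decides nothing here, since 0 of its 16 genes were above background on all Naive and Memory arrays. RNA of monocytes in place of part of the B cell RNA is a candidate explanation that these data cannot decide. The rise of 19 of 19 measured monocyte genes restates the pattern. Of them, CST3, LYZ, S100A9 and CD14 stood at 14.03, 14.01, 13.87 and 13.70 in Orc against 10.79, 11.87, 10.65 and 10.43 in Memory. Of the 19, 14 were above background on all Naive and Memory arrays too, and 0 are on another list. The selection for CD19 that the labels give should remove monocytes, as would a gate on CD20 or CD27, while monocytes, as background, also express ITGAM. However, CD27 was above background on only 1 of 3 Orc arrays, and CD79A stood at 8.67 ± 1.41 in Orc against 12.70 ± 0.09 in Memory. The pan B cell score was 7.35, 7.67 and 7.01 on Orc replicate 1, 2 and 3, while the monocyte score was 11.98, 11.96 and 12.07. A difference between the subsets themselves, with B lineage cells that transcribe monocyte genes and fewer B cell genes, stays open and was not tested, since bulk arrays do not show which cells held the RNA.

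On the Sec arrays the T cell list was higher than on any other array, at 8.96 ± 0.29 against 6.67 ± 0.14 in Memory. A smaller share of B cell RNA that raised every other type alike is argued against by the monocyte list, whose median changed by 0.37 beside 2.70 for the T cell list. The NK cell list rose too, with a median of 2.82 and 7 of 9 genes past the threshold, but its list test did not pass with an estimated correlation (adjusted p = 0.12). Over the Memory mean its score rose by 3.83, 1.10 and 3.04 on Sec replicate 1, 2 and 3, and that of the T cell list by 2.40, 1.96 and 2.51. Scores of the monocyte list were 10.01, 8.25 and 9.96 on Sec replicate 1, 2 and 3, so Sec replicate 2 lowers its median. The rise of the T cell score over the Memory mean exceeded that of the monocyte score on each Sec array, by 1.30, 2.62 and 1.47. RNA of T cells in the sample is a candidate explanation that these data cannot decide. The rise of 16 of 16 measured T cell genes restates the pattern. Of them, CD247, IL7R and CD3D stood at 11.04, 10.62 and 10.33 in Sec against 7.66, 6.79 and 6.63 in Memory. Of the 16, 0 were above background on all Naive and Memory arrays, and 0 are on another list. Members dim outside Sec could pass the filter through the Sec arrays alone, so the 16 of 16 is partly set by the filter. As background, T cells also express CD27 and SPN, while the selection for CD19 that the labels give, or a gate on CD20, should remove T cells. A difference between the subsets themselves, with B cells that transcribe T cell genes, stays open and was not tested.

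Other splits of the same arrays were counted for each number of changed genes. In the pairwise comparisons 6 arrays allow 10 splits, which are too few for a share under 0.05. The real split gave 55 genes in Memory against Naive, 644 in Sec against Naive, 3524 in Orc against Naive, 3417 in Orc against Memory and 2562 in Orc against Sec, and the highest other split gave 1, 2, 0, 0 and 1, with 1 split as large in each, the real one included. In Sec against Memory the real split gave 245 and the highest other gave 308, so that 2 of 10 splits were as large. That split exchanges Memory replicate 3 and Sec replicate 2 and follows the monocyte list score. Whether this gave rise to the count was not tested. For the mean of Sec and Orc against the mean of Naive and Memory 1 of 100 splits was as large, with 3275 genes against 3249 at most in the others, and for any of 4 groups 2 of 100, with 3603 against 3767. The share of splits was under 0.05 for these 2 results, but the counts of the real split and of the highest other lie close together. The count therefore does not tell the real grouping from some other groupings, and chance is not excluded.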

How the results depend on the processing

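Normexp, median centring and the removal of marker genes of other cell types were chosen after seeing the data. In the order Memory against Naive, Sec against Naive, Sec against Memory, Orc against Naive, Orc against Memory, Orc against Sec, the mean of Sec and Orc against the mean of Naive and Memory, and any of 4 groups, the genes changed were 55, 644, 245, 3524, 3417, 2562, 3275 and 3603. With only genes above background on all 12 arrays, 4288 were tested and 6, 244, 31, 1900, 1828, 1283, 1739 and 1868 changed, and with a 2-fold threshold 31, 178, 96, 1249, 1188, 909, 520 and 1358; both settings leave fewer genes by construction. With no filter 31 genes changed in Memory against Naive, among 19949 tested. With only the 6 arrays compared, the first 3 comparisons gave 24, 272 and 46. Orc against Naive, Memory and Sec then gave 3733, 3330 and 2536, near their main counts. Fewer samples estimate the spread in this setting, but the cause of the lower first 3 counts was not tested. Array weights raised Sec against Naive to 1361 and Sec against Memory to 575; the cause was not tested. The other genewise counts stayed within 1.5 times under no filter, the weaker background limit, every probe tested, normexp, median centring and removal of marker genes. Left out in turn, single arrays gave 20 to 169, 243 to 939, 89 to 772, 2959 to 3673, 2804 to 3579, 1913 to 2653, 2804 to 3517 and 2875 to 3788 genes. The largest of the first 3 counts came without Memory replicate 3 (169) and without Sec replicate 2 (939 and 772).

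The lists that passed numbered 4, 10, 11, 6, 5, 8 and 9 in the first 7 comparisons, and 2, 3, 1, 0, 0, 0 and 0 with an estimated correlation: the naive and memory B cell lists in Memory against Naive, these and the T cell list in Sec against Naive, and the T cell list in Sec against Memory. With normexp the ribosomal protein list lost its call in Orc against Naive (adjusted p = 0.057), as did the ribosomal protein and memory B cell lists in the mean comparison (adjusted p = 0.075 and 0.072), and the erythroid list gained one in Sec against Memory (adjusted p = 0.036). Single arrays left out gave list counts of 3 to 5, 9 to 11, 9 to 11, 5 to 7, 4 to 6, 8 to 10 and 6 to 10. Of 280 named calls of a gene in a comparison, 231 held under every alternative that tested the gene. The others, 49, were lost under at least 1, and none reversed. Of all 313 pairs, 97 were unchanged and 4 weaker with genes above background on all 12 arrays, and the rest were not tested there. Of 33 uncalled ones, 7 gained a call under at least 1. SPN gained one in Sec against Naive, Sec against Memory and Orc against Naive, and TCL1A in Sec against Memory. MS4A1 gained one in Sec against Memory, Orc against Naive and the mean comparison.

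The labels give the groups the same replicate numbers, but no sign was seen that the numbers pair the samples. Of 18 pairs of arrays with the same number, 5 had deviations correlated above 0.1 (median -0.067, and 0.004 for pairs with other numbers), and 0 of 12 arrays correlated best with its own number. Other differences between arrays could hide a pairing, so it is not excluded. With the replicate number as a block, Memory against Naive gave 33 and Sec against Memory 141 genes, the other counts stayed within 1.5 times, as did the list counts. The neqc normalization, the quantile normalization of non-normalized signals and a slide block were not run, since no column of those signals matches a sample and no slide is given. A high floor limits the dim genes: 16.6% to 24.6% of the probes lay above background.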

Other observations

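The correlations of list scores in this part were chosen after the scores were seen. In the cytokine and chemokine list, 6 of 14 genes were higher and 5 lower in Orc than in Sec, and the list did not pass in any comparison (in Orc against Sec median -0.35, mean 0.26 of opposite sign, list test adjusted p = 0.89). IL6 was lower on average in Sec and Orc than in Naive and Memory, at -1.62 ± 0.21 (adjusted p = 0.00017). The list of CD11c and T-bet B cell genes rose in 5 of 12 and fell in 2 in Orc against Sec (adjusted p = 0.5), with FGR at 2.06 ± 0.28 (adjusted p = 0.00023). In the antigen presentation list, 6 of 17 genes rose and 2 fell in the same comparison (adjusted p = 0.06), with IFI30, a thiol reductase of antigen processing, at 2.58 ± 0.36 (adjusted p = 0.00024).

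The type I interferon list scored 8.02 ± 0.51 in Naive, 8.10 ± 0.32 in Memory, 8.26 ± 0.43 in Sec and 8.69 ± 0.81 in Orc, and ranged from 8.15 to 9.62 within the Orc arrays; it passed in no comparison, and 7 of its 17 genes rose in Orc against Naive. The erythroid list scored 9.78 ± 0.57 in Naive, 8.53 ± 1.68 in Memory, 9.66 ± 1.55 in Sec and 8.97 ± 1.19 in Orc, ranging from 6.66 to 11.45 over the 12 arrays, and passed in no comparison, and HBD, above background on no Naive array, was at least 1.12-fold higher in Orc than in Naive (adjusted p = 0.0073). Of the small lists, TYMS of the cell cycle list was at least 1.24-fold higher in Sec than in Memory (adjusted p = 0.027), a call lost without Memory replicate 1, Memory replicate 3 and Sec replicate 3, and with the replicate block and with only the 6 arrays compared (adjusted p up to 0.17 over its alternatives). TCF4 of the plasmacytoid dendritic cell list, which B cells also express, was lower in Orc than in Memory, at -2.36 ± 0.19 (adjusted p = 8.3e-06), and S100P of the neutrophil list was at least 1.24-fold higher (adjusted p = 0.0026). The unfolded protein response list scored 8.52 ± 0.01 in Naive, 8.48 ± 0.04 in Memory, 8.70 ± 0.08 in Sec and 8.68 ± 0.02 in Orc.

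The monocyte list also differed between arrays within groups other than Orc, from 8.25 to 10.01 over the 9 Naive, Memory and Sec arrays. Over these arrays its score correlated with that of the platelet list (Pearson r = 0.93, exact permutation p = 0.0014, adjusted 0.0069; Spearman rho = 0.83, exact permutation p = 0.0083, adjusted 0.041, of 5 relations), and r was 0.91 without the 2 arrays farthest from the median. With the T cell, NK cell, pan B cell and erythroid lists r was 0.32, 0.60, -0.53 and -0.26 (exact permutation p = 0.35, 0.091, 0.16 and 0.52, adjusted 0.44, 0.23, 0.26 and 0.52) and rho 0.57, 0.62, -0.40 and -0.45 (exact permutation p = 0.12, 0.086, 0.29 and 0.23, adjusted 0.2, 0.2, 0.29 and 0.29), so none of these 4 relations passed before centring. After centring each group, r was 0.95 with the platelet list, 0.96 with the T cell list and 0.91 with the NK cell list (exact permutation p = 0.037, 0.032 and 0.0093 over 216 rearrangements within groups, 2-sided, adjusted 0.062, 0.062 and 0.046), -0.71 with the pan B cell list and -0.51 with the erythroid list (exact permutation p = 0.21 and adjusted 0.21 for each). A hypothesis is that other mononuclear blood cells and platelets were carried over together to a degree that differed between preparations, and the split of Sec and Memory arrays that gave 308 genes may reflect this. Whether red cell RNA came along cannot be told apart on 9 arrays at r = -0.51, and a difference between donors was not tested. T cell and NK cell genes lay near background on the Naive and Memory arrays, which limits their 2 correlations.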
